A study of Mus musculus with 28 samples.

How the data were processed

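The labels describe liver samples of 28 mice, 7 in each of 4 groups: WT and HZ, each with vehicle or WY. Per the labels, livers were flash frozen, RNA was taken up with Trizol and libraries were made with the NEBNext Ultra kit. The sex of the animals is not given in the sources used here. Per the submitters' processing notes, reads were handled with STAR 2.5.0a and HTSeq 0.6.1p1 on mm10, and DESeq2 1.18.1 is named as well. The annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty, and genes with near-identical copies are represented by the reads that could be placed uniquely. The values deposited by the authors are raw counts of reads per gene symbol without normalization, in a table of the 14 vehicle libraries and a table of the 14 WY libraries. Animal numbers served as replicate numbers, and no number occurs in more than 1 group, so animals were not paired.

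The vehicle table had 23423 rows, and the WY table had 23425. Both ended in 5 HTSeq summary rows, which were kept out of library sizes and tests. Of all reads in the table, 35.8 to 42.6% per library were in the row of reads not placed uniquely, 6.35 to 9.08% in no gene and 0.413 to 0.511% in more than 1 gene. The share in no gene was 8.45 ± 0.114% in WT vehicle, 8.43 ± 0.418% in HZ vehicle, 6.75 ± 0.321% in WT WY and 7.11 ± 0.469% in HZ WY (SD, n = 7). The deposited tables hold 25 gene names turned into dates by a spreadsheet (25 rows of the vehicle table and 27 of the WY table, with 2 names present more than once). These rows could not be assigned and were left out, with 0.147 to 0.160% of the gene counts in vehicle and 0.224 to 0.246% in WY libraries. The other 23393 symbols were the same in both tables. Each library had 15795201 to 20020078 gene counts, and 15015 to 16606 genes were detected per library.

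Counts were analysed with R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 12607, normalized by TMM, and tested in edgeR 4.0.16 with robust quasi-likelihood fits on all 28 libraries (24 residual degrees of freedom), with a mean per group and 5 contrasts: HZ against WT under vehicle, HZ against WT under WY, WY against vehicle in WT, WY against vehicle in HZ, and the interaction. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. SE is the absolute log2 fold change over the root of the F statistic. Log2 CPM values used a prior count of 2. The replicates of a group differed by more than counting error: the chi-square per degree of freedom between pairs, 21 pairs per group, ran from 10.9 to 113.

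Before the data were examined, 40 gene lists of liver pathways, stress programmes and cell type markers were fixed, with 727 members. Of these, 709 were found, 10 of them under an older symbol, and 36 lists had at least 3 tested members. The lists without a test were mitochondrial DNA transcripts, T and NK cells, adipocytes and exocrine pancreas. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, and p was adjusted over the 36 lists of a contrast. With the estimated correlation camera called 0 lists in every contrast, and its smallest adjusted p was 0.167, 0.663, 0.264, 0.187 and 0.628 in the order of the contrasts above, against 15, 11, 13, 12 and 9 lists with the preset one and 6, 2, 19, 22 and 0 with fry. For each list, the mean log2 CPM of its members per animal gave a test of HZ against WT response with 100000 permutations of genotype within treatment. The named genes were set before the data were examined: Sirt6, 12 textbook PPARα targets, the 10 largest rises and falls that pass with a mean of at least 5 CPM and are not unnamed gene models, and from each list the members with the smallest p, with the members of highest level where none passes. For the interaction these are the 5 genes with the smallest p, given with their WY effects. Some of the named genes are not reported here. Positions are from GENCODE M21, on GRCm38, and symbols follow the deposited tables (Agxt2l1 is now Etnppl and Rqcd1 is Cnot9).

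The calls were tested on simulated data made from the counts of these libraries, with about 200 genes changed per contrast. At a log2 change of 0.5, 64% were recovered for HZ against WT under vehicle, 54% under WY, 54% and 63.3% for WY in WT and HZ, and 51.0% for the interaction. At a log2 change of 1 the shares were 80%, 78%, 88%, 80% and 82%. False calls were 7 of 179, 8 of 173, 7 of 175, 6 of 177 and 10 of 171, and 0 of 36 lists were called. The simulated genes varied independently of each other. These counts therefore do not measure false calls among genes that vary together, lists included.

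Alternatives planned before the data were examined were DESeq2 size factors, DESeq2 1.42.0, limma with voom quality weights, no filter on low counts, a mean of at least 5 CPM, only the groups compared, a fold threshold of 1 on the log2 scale, a term for animals numbered 71 to 78, and leaving out each library. Chosen after the results were seen were leaving out 5 HZ libraries that stand apart on the second principal component (vehicle 30 and 38, WY 14, 15 and 21), removing a trend on transcript length or GC content (known for 12506 genes, 99.2%), a clock score as a covariate, and using only vehicle animals numbered 29 to 39. Where the HZ animals left out were the highest or lowest of a list, its difference shrinks by construction. Such values show how much of the difference these animals carried. A covariate for sex was planned only for the case of mixed sexes and was not run, as Y-linked genes were expressed in all libraries.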

Results

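Liver RNA was sequenced from 28 mice of the 129svj strain aged 11 to 13 months. The animals were wild type (WT) or heterozygous for Sirt6 (HZ). Sirt6 is a nuclear NAD-dependent deacylase that acts on histones. Each animal received by mouth either 0.5% carboxymethylcellulose, the vehicle, or WY-14643 (WY) at 50 mg/kg, and the liver was taken 12 h later. WY-14643 is a synthetic agonist of PPARα, the nuclear receptor that controls hepatic genes of fatty acid oxidation. Each of the 4 groups held 7 animals with a library each. Counts assigned to gene symbols came to 16626530 to 19539233 per library in WT vehicle and 16769148 to 20020078 in HZ vehicle. They came to 15795201 to 18337517 in WT WY and 16777463 to 19940067 in HZ WY. Levels are given as CPM, counts scaled to a common library total, mean ± SD with n = 7 per group, and changes as log2 fold change ± SE from a fit of all 28 libraries, with p adjusted over the 12607 genes tested.

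Sirt6 (GRCm38 chromosome 10, 81621785 to 81627797, minus strand) was lower in HZ livers under both treatments. Under vehicle it stood at 2.38 ± 0.615 CPM in WT and 1.21 ± 0.180 CPM in HZ, a log2 fold change of -0.97 ± 0.17 (adjusted p = 0.00696). Under WY it stood at 3.31 ± 0.685 CPM in WT and 1.61 ± 0.359 CPM in HZ, a log2 fold change of -1.04 ± 0.16 (adjusted p = 0.00721). Two-sided exact permutation tests on log2 CPM, over 3432 splits of 7 against 7, gave p = 0.000583 under vehicle and p = 0.00117 under WY. The gene was sparsely counted, with 15 to 79 reads per library. Under vehicle it did not pass over all genes with only the vehicle libraries (-0.96, adjusted p = 0.173), without 5 HZ libraries that stood apart (-1.04, adjusted p = 0.0549) or with animals 29 to 39 only (-0.96, adjusted p = 0.0610), at folds of like size. WY raised Sirt6 in WT by 0.47 ± 0.16 (adjusted p = 0.0131), while the value in HZ was 0.40 ± 0.18 (adjusted p = 0.0572), and the test of the difference between these changes gave -0.08 ± 0.24 (adjusted p = 0.937).

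The comparison of HZ with WT under vehicle asks how the genotypes differed in liver transcripts without the agonist. HZ livers had lower levels of genes that handle fatty acids and lipid droplets. Acot3, a peroxisomal acyl-CoA thioesterase (chromosome 12, 84052144 to 84060402), fell by 2.63 ± 0.55 (adjusted p = 0.0181), from 62.7 ± 35.5 CPM in WT to 10.2 ± 11.4 CPM in HZ. G0s2, an inhibitor of the triglyceride lipase ATGL (chromosome 1, 193272161 to 193273217), fell by 2.18 ± 0.43 (adjusted p = 0.0134), from 160 ± 112 to 35.3 ± 17.6 CPM. Plin2, the main coat protein of lipid droplets in hepatocytes (chromosome 4, 86648386 to 86670060), fell by 1.27 ± 0.27 (adjusted p = 0.0183), from 939 ± 412 to 389 ± 207 CPM. The cytosolic thioesterase Acot1 (chromosome 12, 84009490 to 84018371) fell by 1.55 ± 0.38 (adjusted p = 0.0345), from 369 ± 173 to 126 ± 102 CPM. Acot1, Acot2, Acot3 and Acot4 are close copies of each other, and only uniquely placed reads were counted. Acot2 (-1.85 ± 0.46), Acot4 (-1.39 ± 0.31), the keratin Krt23 (-2.08 ± 0.36), Clstn3 (-1.49 ± 0.37), Cbfa2t3 (-1.45 ± 0.31), Spon2 (-1.40 ± 0.30) and the vesicular glutamate transporter Slc17a8 (-1.32 ± 0.35) also fell.

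Fewer genes were higher in HZ under vehicle. The largest rises among the named genes were those of Tifa, an adaptor of innate immune signalling (1.45 ± 0.32, adjusted p = 0.0200), its upstream kinase Alpk1 (1.23 ± 0.29, adjusted p = 0.0307) and Ddit4, a stress-induced inhibitor of mTORC1 (1.20 ± 0.29, adjusted p = 0.0307). Plxnb1 (1.13 ± 0.30), Adamts7 (1.09 ± 0.27), the BCL2 family member Bok (0.89 ± 0.17), the immunoproteasome subunit Psmb9 (0.67 ± 0.17), Irf5 (0.65 ± 0.16), Nedd9 (0.63 ± 0.17) and Ttc39c (0.53 ± 0.12) rose as well. In all, 261 genes passed, 38 higher and 223 lower in HZ, and 35 of them differed at least by a log2 of 1.

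Some of the lower genes belong to gene lists fixed in advance. Of 27 tested genes of peroxisomal fatty acid oxidation, 15 fell and 12 did not pass, and 22 were lower adjusted over the list alone. Among them were Decr2 (-0.42 ± 0.07), the peroxisome proliferation factor Pex11a (-1.25 ± 0.25) and the fatty acid transporter Slc27a2 (-0.36 ± 0.08). Of 23 genes of mitochondrial fatty acid oxidation 10 fell and 13 did not pass, with 17 lower adjusted over the list alone, and examples were the carnitine carriers Slc25a20 (-0.68 ± 0.14) and Slc22a5 (-1.05 ± 0.23) and the carnitine palmitoyltransferase Cpt2 (-0.71 ± 0.15). Of 35 genes of lipid uptake, storage and release 8 fell and 27 did not pass, with 15 lower adjusted over the list alone, including the monoglyceride lipase Mgll (-0.90 ± 0.16) and the droplet protein Fitm2 (-0.81 ± 0.16). The camera test placed these 3 lists below the other genes with adjusted p = 1.3e-18, 3.8e-14 and 5.2e-08. With an estimated correlation each of the 3 lists had an adjusted p = 0.167.

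Other lists went the same way with fewer members passing. Of 12 genes of microsomal omega oxidation 1 fell, the aldehyde dehydrogenase Aldh3a2 (-0.73 ± 0.20), and 6 were lower adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.53 with an estimated correlation). The fatty acid hydroxylases Cyp4a10 and Cyp4a14, whose reads are shared with close copies, had values of -0.84 ± 0.25 (adjusted p = 0.0691) and -0.996 ± 0.30 (adjusted p = 0.0737). Of 8 genes of ketone body synthesis 1 fell, the monocarboxylate transporter Slc16a1 (-0.87 ± 0.23), with 3 lower adjusted over the list alone. Camera gave this list an adjusted p = 0.0084, or adjusted p = 0.32 with an estimated correlation. Of 14 heat shock genes 1 fell, Hsp90aa1 (-0.47 ± 0.13), while the co-chaperone Dnaja1 had -0.27 ± 0.08 (adjusted p = 0.0507), with 6 lower adjusted over the list alone (camera adjusted p = 4e-05, adjusted p = 0.33 with an estimated correlation). Of 27 nuclear genes of oxidative phosphorylation 1 fell, Cox5b (-0.25 ± 0.06), with 1 lower adjusted over the list alone (camera adjusted p = 1.1e-07, adjusted p = 0.53 with an estimated correlation). HZ vehicle animal 38 had the lowest mean of this list, and the difference of the means went from -0.13 to -0.0937 without it and to -0.0795 without animals 30 and 38.

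Inflammatory genes stood higher in some HZ vehicle livers. Of 28 acute phase and complement genes 0 passed in edgeR over all genes and 15 were higher adjusted over the list alone (camera adjusted p = 1.9e-05, adjusted p = 0.56 with an estimated correlation). Saa2, a serum amyloid A, had 4.04 ± 1.24 (adjusted p = 0.0866), but -0.0527 without HZ vehicle animal 30, -0.0776 with DESeq2 and -0.36 without the 5 HZ libraries. Lcn2, lipocalin 2, had 3.50 ± 1.03 (adjusted p = 0.0707), and Crp had 0.35 ± 0.10 (adjusted p = 0.0648). The values rested on few animals: HZ vehicle animal 30 had a mean log2 CPM of 10.6 over this list, and the next highest HZ vehicle animal had 9.28. Of 14 Kupffer cell and macrophage markers 0 passed in edgeR, also adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.56 with an estimated correlation), with Cd163 at 0.59 ± 0.23 (adjusted p = 0.168) and Timd4 at 0.65 ± 0.30 (adjusted p = 0.252). The difference of the means of the acute phase list went from 0.40 to 0.14 without animal 30 and to 0.0205 without 30 and 38, and that of the macrophage list from 0.29 to 0.17 and 0.0429. Without the 5 HZ libraries that stood apart on the second principal component, which include vehicle animals 30 and 38, camera gave the acute phase list adjusted p = 0.137 and the macrophage list adjusted p = 0.456. Of 24 genes of cholesterol synthesis and uptake 0 passed in edgeR, also adjusted over the list alone, and camera placed the list higher in HZ with adjusted p = 0.0016 (adjusted p = 0.57 with an estimated correlation), with Mvk at 0.40 ± 0.16 (adjusted p = 0.194) and Hmgcs1 at 0.49 ± 0.25 (adjusted p = 0.312).

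In the 3 lipid lists the animals lay further apart under vehicle than under WY: the mean log2 CPM had an SD of 0.247 in WT vehicle and 0.243 in HZ vehicle, against 0.0499 in WT WY and 0.0895 in HZ WY. That mean was lower in HZ than WT vehicle animals by a log2 difference of -0.46 (two-sided exact permutation p = 0.00583, 7 against 7). The 3 lists were pooled after their fall in these animals had been seen, and this p is not adjusted for that choice. Gene by gene the calls depended on the libraries used. EdgeR on the 14 vehicle libraries alone called 0 genes (1889 at an unadjusted p under 0.05). The main fit shares its estimate of spread over all 28 libraries. With the vehicle libraries alone, the SE of 34 genes called and named here grew (median ratio 1.26). Their folds had a median ratio of 0.995, which follows from fitting a mean per group. The SE reported for these genes thus understate their spread under vehicle. DESeq2 on all 28 called 521 genes and limma with voom quality weights 701, and leaving out a library at a time gave 43 to 650. In the vehicle groups 3 WT animals and 1 HZ animal carry numbers from 71 to 78, and with a term for these animals 69 genes passed, 67 of them shared with the 261.

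**Figure D1:**
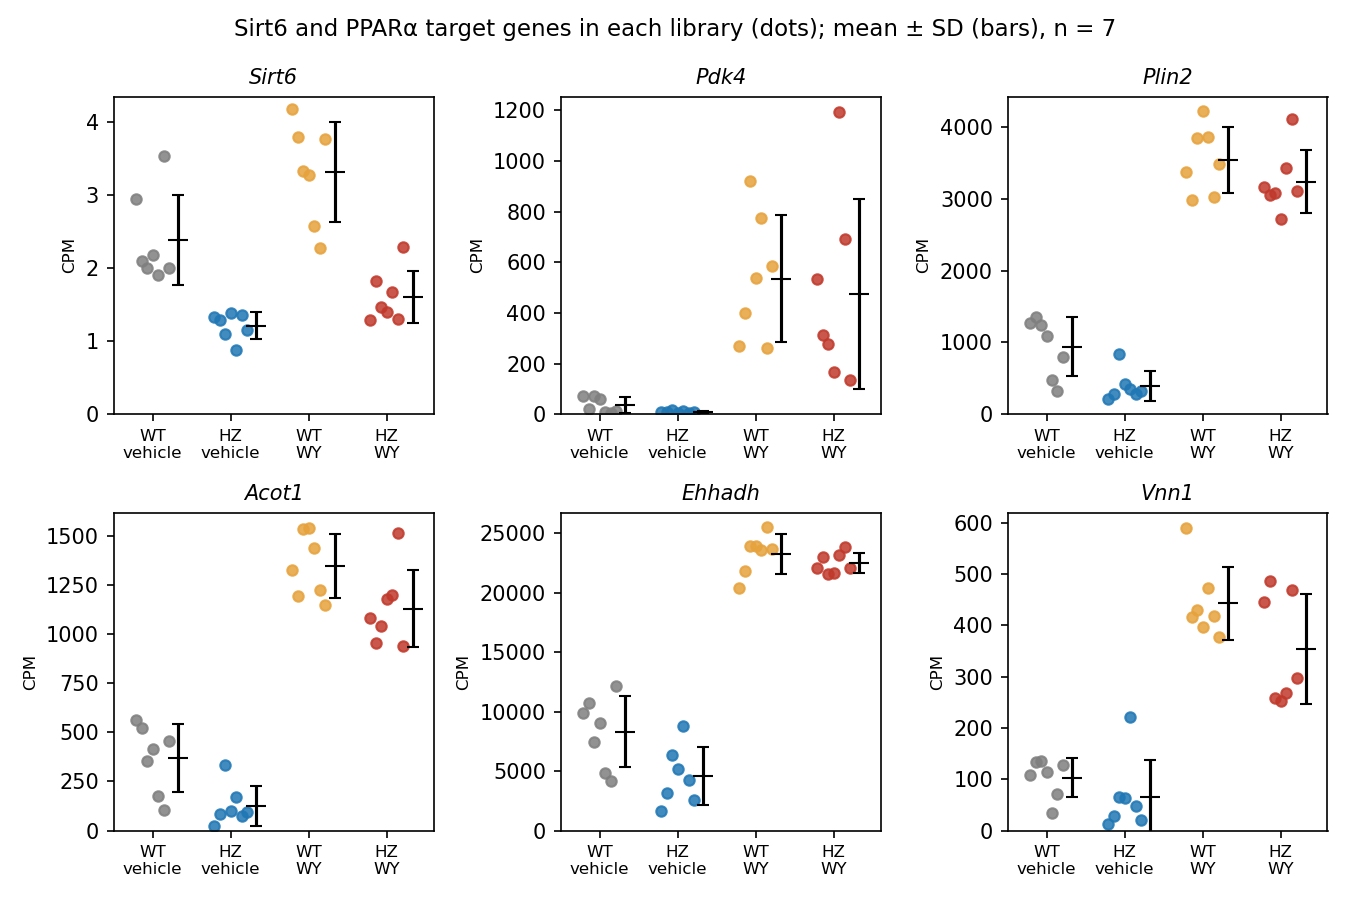
CPM of Sirt6 and 5 PPARα target genes in each library, by group (dots), with the mean ± SD of each group of 7 (bars). Sirt6 is lower in HZ under both treatments, and Plin2 stands at 939 CPM in WT vehicle, 389 CPM in HZ vehicle, 3544 CPM in WT WY and 3241 CPM in HZ WY.

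The comparison of HZ with WT under WY asks whether the genotypes still differed once PPARα had been driven. Rassf4, a RAS association domain protein, rose by 1.00 ± 0.20 (adjusted p = 0.0134), from 7.50 ± 1.25 CPM in WT to 15.0 ± 4.81 CPM in HZ. Dnajb1, a co-chaperone of Hsp70, fell by 0.59 ± 0.13 (adjusted p = 0.0175), from 69.2 ± 13.7 to 45.9 ± 8.29 CPM. Tnfaip2, a TNF-induced gene, rose by 0.90 ± 0.19 (adjusted p = 0.0176), and Esr1, oestrogen receptor alpha, rose by 0.77 ± 0.20 (adjusted p = 0.0379). Further rises were those of Arhgap30 (1.00 ± 0.24), Asap2 (0.97 ± 0.22), the ubiquitin ligase Rnf125 (0.85 ± 0.19), the transporter Abca9 (0.80 ± 0.16), Heg1 (0.79 ± 0.15), Atxn1 (0.76 ± 0.16) and Atp11a (0.75 ± 0.21). Further falls were those of the fatty acid transport protein Slc27a1 (-0.51 ± 0.13), Hopx (-0.46 ± 0.13), the lipid droplet dehydrogenase Hsd17b11 (-0.45 ± 0.10), Tmem223 (-0.43 ± 0.09), Llph (-0.43 ± 0.11), Rpl13 (-0.41 ± 0.10), which has many pseudogene copies, and Cmc2 (-0.40 ± 0.09). In all, 398 genes passed, 179 higher and 219 lower in HZ, and 13 differed at least by a log2 of 1. The balance moved with the processing: 203 were higher and 480 lower with DESeq2 size factors, 398 and 725 with DESeq2, and 83 and 70 without a filter on low counts. Of 31 genes called in this comparison and named in the text, 25 lost their call without the 5 HZ libraries that stood apart. With a trend on transcript length removed 15 lost it.

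Some chaperone and respiratory chain genes were lower in HZ under WY. Of 14 heat shock genes 3 fell and 11 did not pass, with 7 lower adjusted over the list alone, and besides Dnajb1 these were the Hsc70 gene Hspa8 (-0.41 ± 0.11) and Dnaja1 (-0.40 ± 0.07). Camera gave this list adjusted p = 2e-05, or adjusted p = 0.66 with an estimated correlation. Of 27 nuclear genes of oxidative phosphorylation 7 fell and 20 did not pass, with 16 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.6e-10, adjusted p = 0.66 with an estimated correlation). Examples were the complex IV subunits Cox6a1 (-0.34 ± 0.07) and Cox5a (-0.22 ± 0.06), the complex I subunit Ndufs3 (-0.20 ± 0.05) and the complex II subunit Sdhb (-0.25 ± 0.06). HZ WY animals 14, 15 and 21 had the lowest means of this list in their group, and without them the difference of the means went from -0.14 to -0.0942. Leaving out the lowest animals of HZ alone shrinks this difference by construction. These are short transcripts, and over all genes the median log2 fold change was -0.09 in the shortest 25% of transcripts and 0.10 in the longest 25%. The shortest 25% held 134 of the 219 lower genes, and the longest 25% held 107 of the 179 higher genes.

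Fewer members of the fatty acid oxidation lists passed between genotypes under WY than under vehicle. The test of a difference between the treatments, the interaction, passed for 0 genes in edgeR (1182 at an unadjusted p under 0.05; 3 with DESeq2, 1 with voom) and gave the peroxisomal list a permutation adjusted p = 0.433. Of 27 genes of peroxisomal fatty acid oxidation 2 fell, Mlycd (-0.27 ± 0.07), which encodes malonyl-CoA decarboxylase, and the thiolase Acaa1a (-0.26 ± 0.07), with 3 lower adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.66 with an estimated correlation). Of 23 genes of mitochondrial fatty acid oxidation 0 passed in edgeR, also adjusted over the list alone, and the list median was -0.15 (camera adjusted p = 0.00016, adjusted p = 0.66 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake 1 rose, Srebf2, the transcription factor of the pathway (0.38 ± 0.08, adjusted p = 0.0176), with 9 higher adjusted over the list alone (camera adjusted p = 2e-05, adjusted p = 0.66 with an estimated correlation). Hmgcs1 (0.76 ± 0.25, adjusted p = 0.0748) and Lss (0.69 ± 0.23, adjusted p = 0.0751) did not pass over all genes, and without WT WY animal 10 the difference of the list means went from 0.36 to 0.22. Of 15 pericentral hepatocyte genes 2 rose, the Wnt feedback genes Axin2 (0.60 ± 0.16, adjusted p = 0.0441) and Rnf43 (0.50 ± 0.13), and the list as a whole was not called (camera adjusted p = 0.59). The clock gene Rora rose (0.35 ± 0.09) and the clock output gene Dbp had -1.49 ± 0.50 (adjusted p = 0.077). The clock score ran from -0.224 to 3.38 in WT WY animals and from -1.07 to 1.85 in HZ WY animals. Genotype and clock score were thus not balanced under WY. With this score as a covariate 1038 genes passed between HZ and WT under WY.

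Leukocyte markers stood higher in some HZ livers under WY. Of 14 Kupffer cell and macrophage markers 0 passed in edgeR over all genes and 11 were higher adjusted over the list alone (camera adjusted p = 2e-05, adjusted p = 0.66 with an estimated correlation). Clec4f, a Kupffer cell lectin, had 0.41 ± 0.12 (adjusted p = 0.0553), and Csf1r, the macrophage colony-stimulating factor receptor, had 0.75 ± 0.22 (adjusted p = 0.0576). Of 5 neutrophil and monocyte markers 0 passed in edgeR over all genes and 4 were higher adjusted over the list alone (camera adjusted p = 0.0082, adjusted p = 0.66 with an estimated correlation), with the monocyte chemokine receptor Ccr2 at 1.56 ± 0.47 (adjusted p = 0.0628) and S100a8 at 1.67 ± 0.53 (adjusted p = 0.0687). H2-Aa, an MHC class II gene, had 1.27 ± 0.42 (adjusted p = 0.0753). Without HZ WY animal 21 Ccr2 had 0.88 and H2-Aa 0.68, and without animal 15 S100a8 had 1.03. Of 28 acute phase and complement genes 0 passed over all genes and 4 were higher adjusted over the list alone, with Lcn2 at 3.77 ± 1.10 (adjusted p = 0.0576) and complement C3 at 0.39 ± 0.12 (adjusted p = 0.0652). Camera gave the acute phase list adjusted p = 0.00037, or adjusted p = 0.66 with an estimated correlation. Without the 5 HZ libraries that stood apart, WY animals 14, 15 and 21 among them, camera gave the macrophage list adjusted p = 0.404, the neutrophil list adjusted p = 0.470 and the acute phase list adjusted p = 0.0170. Without animals 14, 15 and 21 the difference of the means went from 0.52 to 0.0959 for the macrophage list, from 0.94 to 0.23 for the neutrophil list and from 0.56 to 0.23 for the acute phase list.

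Without those 5 libraries 48 genes passed between HZ and WT under WY, and with a trend on transcript length removed 142 passed, 128 of them shared with the 398. Leaving out a library at a time gave 74 to 977 genes, and DESeq2 called 1123. Sirt6, Dnajb1, Hsd17b11 and Dnaja1 were called in every leave-one-out and every setting that tested them, apart from the added fold threshold. Sirt6 lay below a mean of 5 CPM and was not tested in the setting with that bound.

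**Figure D2:**
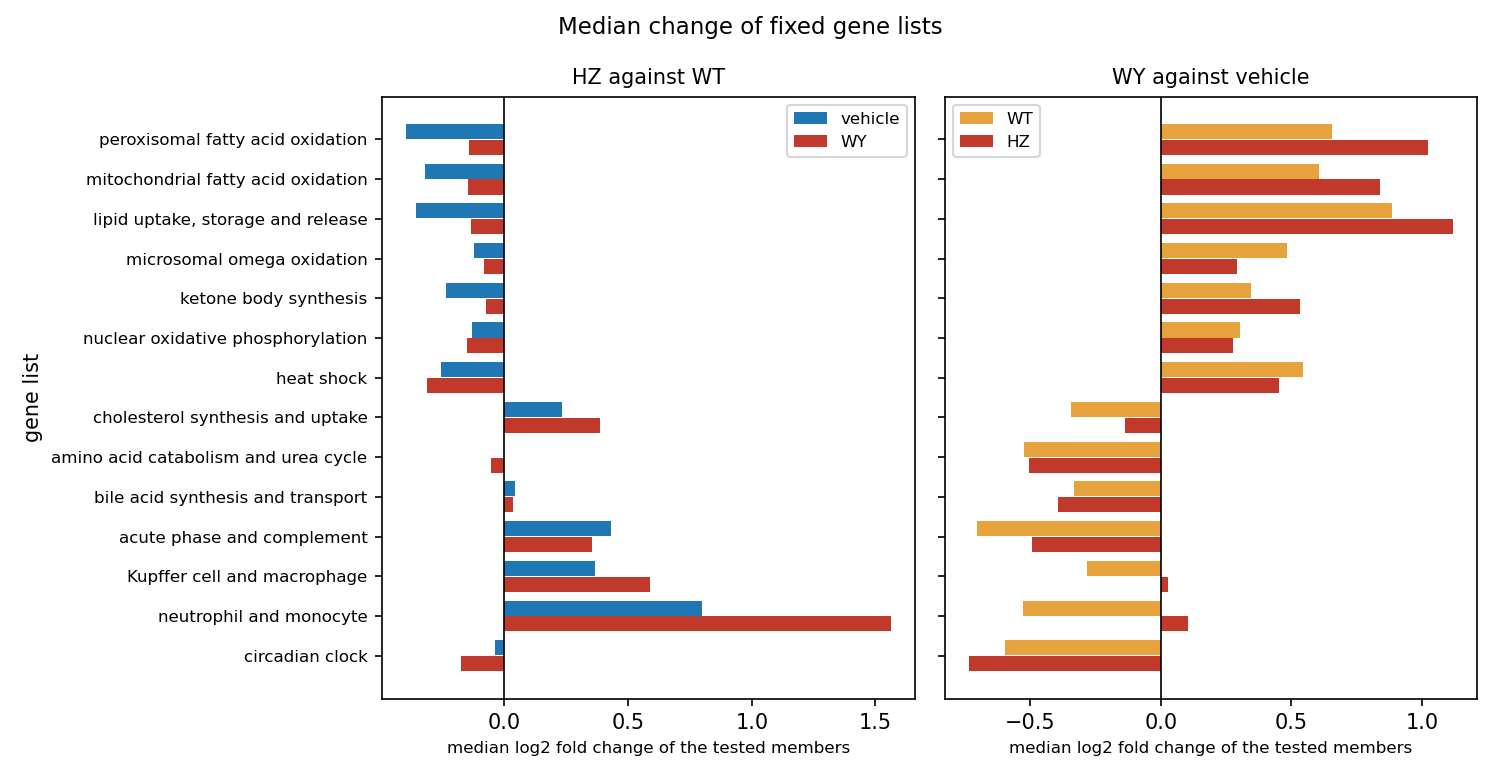
Median log2 fold change of 14 gene lists fixed in advance, in the comparisons of genotype and of treatment (left and right panels, log2 scale). The peroxisomal list has a median of -0.40 in HZ against WT under vehicle, -0.14 under WY, 0.66 with WY in WT and 1.02 with WY in HZ.

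The comparison of WY with vehicle in WT livers gives the response to the agonist in wild type animals. WY raised genes of fatty acid oxidation and lipid storage and lowered genes of amino acid breakdown. Pdk4, the kinase that shuts off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose by 3.89 ± 0.59 (adjusted p = 4.95e-06), from 36.2 ± 30.4 CPM to 536 ± 249 CPM. Cidec, a lipid droplet fusion protein, rose by 3.54 ± 0.28 (adjusted p = 2.94e-10), from 3.74 ± 0.897 to 43.7 ± 18.7 CPM. Plin2 rose by 1.92 ± 0.28 (adjusted p = 2.05e-06), from 939 ± 412 to 3544 ± 460 CPM. Cps1, the entry enzyme of the urea cycle, fell by 2.03 ± 0.17 (adjusted p = 2.32e-10). In all, 6815 genes passed (54.1% of those tested), 3454 higher and 3361 lower, and 625 of them changed at least by a log2 of 1. The vehicle and the WY libraries come from separate count tables and separate animal number ranges, so treatment and table cannot be told apart.

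Among PPARα target genes named in advance, WY in WT raised Ehhadh, the peroxisomal bifunctional enzyme (1.48 ± 0.26, adjusted p = 2.07e-05), from 8317 ± 2964 to 23246 ± 1664 CPM. The pantetheinase Vnn1 (2.10 ± 0.43), Acot1 (1.87 ± 0.38), Cyp4a14 (1.00 ± 0.30, adjusted p = 0.00626), Cyp4a10 (0.90 ± 0.25, adjusted p = 0.00315) and the lipoprotein lipase inhibitor Angptl4 (0.52 ± 0.14) rose as well. Cpt1a (0.05 ± 0.08, adjusted p = 0.647) and the hormone gene Fgf21 (0.53 ± 0.35, adjusted p = 0.205) did not pass. Other large rises were those of Adamts15 (3.71 ± 0.42), Cpne5 (3.60 ± 0.47), Lamb3 (2.86 ± 0.37), Cbfa2t3 (2.73 ± 0.29), the muscle isoform of fructose bisphosphatase Fbp2 (2.71 ± 0.29), the fatty acid binding protein Fabp4 (2.65 ± 0.31), Acot2 (2.60 ± 0.47) and Gadd45b (2.43 ± 0.24). Large falls were those of Rgs16 (-3.34 ± 0.52), the uridine phosphorylase Upp2 (-3.25 ± 0.57), the chemokine Cxcl1 (-2.96 ± 0.89, adjusted p = 0.00697), Apol9a (-2.81 ± 0.65) and its close copy Apol9b (-2.44 ± 0.39), Zbtb16 (-2.74 ± 0.50), Agxt2l1 (-2.72 ± 0.33), Slco1a4 (-2.65 ± 0.32), Map2k6 (-2.56 ± 0.33) and Abca8a (-2.53 ± 0.19). Leaving out WT vehicle animal 37 ended the call of Cxcl1 (-1.78, adjusted p = 0.0659), and without WT vehicle animal 76 Apol9a had -1.42 (adjusted p = 0.00464).

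The lists show the breadth of the rise in WT. Of 23 genes of mitochondrial fatty acid oxidation 20 rose and 3 did not pass, also adjusted over the list alone, with the enoyl-CoA isomerase Eci1 (0.93 ± 0.08) and the electron transfer flavoprotein Etfb (0.87 ± 0.07) as examples. Of 27 peroxisomal genes 21 rose, 3 fell and 3 did not pass, also adjusted over the list alone, with Acaa1a at 1.35 ± 0.07 beside Ehhadh. Of 35 genes of lipid uptake, storage and release 26 rose, 3 fell and 6 did not pass (26 and 4 adjusted over the list alone), with Slc27a1 at 2.29 ± 0.15 and the triglyceride lipase Pnpla2 at 1.45 ± 0.12. Camera gave adjusted p = 1.1e-07, 5.1e-06 and 5.8e-07 for these lists, and adjusted p = 0.43, 0.49 and 0.26 with an estimated correlation. Of 27 nuclear genes of oxidative phosphorylation 20 rose and 7 did not pass, also adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.49 with an estimated correlation). Cox6a1 (0.76 ± 0.07) and Cox4i1 (0.64 ± 0.07) were examples. Over all genes the change with WY in WT correlated with log10 transcript length at r = -0.265 and with GC content at r = 0.334. The median of this list was 0.30, with 0.17 once a length trend was removed (16 higher, 3 lower) and 0.22 once a GC trend was removed (21 higher). Of 14 heat shock genes 10 rose and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.0006, adjusted p = 0.43 with an estimated correlation). The mitochondrial chaperonin Hspe1 stood at 0.91 ± 0.09 and Dnaja1 at 0.56 ± 0.08.

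Other liver functions fell with WY in WT. Of 31 genes of amino acid catabolism and the urea cycle 20 fell, 1 rose and 10 did not pass, also adjusted over the list alone (camera adjusted p = 5.1e-06, adjusted p = 0.43 with an estimated correlation). Cps1 and the liver glutaminase Gls2 (-1.48 ± 0.14) were examples. Of 20 genes of bile acid synthesis and transport 12 fell and 1 rose, also adjusted over the list alone, including Akr1d1 (-2.17 ± 0.23) and the bile acid importer Slc10a1 (-0.74 ± 0.09), with camera adjusted p = 0.0033 and adjusted p = 0.26 with an estimated correlation. Of 20 drug metabolism genes under CAR and PXR 11 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.49 with an estimated correlation). Cyp2c29 stood at -0.87 ± 0.14 and the sulfotransferase Sult1d1 at -1.25 ± 0.18. Of 20 clock genes 9 fell and 11 did not pass (8 lower adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.43 with an estimated correlation). Rora stood at -0.74 ± 0.09. Of 28 acute phase and complement genes 14 fell and 14 did not pass, also adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.74 with an estimated correlation). Crp (-0.90 ± 0.10) and Saa4 (-1.52 ± 0.24) were examples. Of 25 interferon response genes 18 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0025, adjusted p = 0.83 with an estimated correlation). Mx2 stood at -1.89 ± 0.27 and Stat2 at -0.39 ± 0.08. WT vehicle animal 76 stood apart in that list, with a mean log2 CPM of 3.80 against 2.42 in the next highest WT vehicle animal, and without it the difference of the list means went from -0.70 to -0.47. Of 24 genes of cholesterol synthesis and uptake 9 fell and 15 did not pass, also adjusted over the list alone, with the sterol carrier Stard4 at -0.81 ± 0.11 and the desaturase Sc5d at -1.13 ± 0.23, and camera gave adjusted p = 0.026 (adjusted p = 0.93 with an estimated correlation), which reached 0.153 when a library was left out. Without WT WY animal 10 the difference of the means of this list went from -0.42 to -0.27.

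The comparison of WY with vehicle in HZ livers gives the response in animals with a lower Sirt6 level. Cpne5, a calcium-dependent membrane-binding protein, rose by 5.84 ± 0.58 (adjusted p = 8.67e-09), and Pdk4 rose by 5.61 ± 0.65 (adjusted p = 7.97e-08), from 9.70 ± 4.44 to 474 ± 375 CPM. Acot3 rose by 4.08 ± 0.58 (adjusted p = 1.72e-06), G0s2 by 3.88 ± 0.46 and Plin2 by 3.06 ± 0.29 (adjusted p = 2.4e-09), the last from 389 ± 207 to 3241 ± 437 CPM. Adamts15 (4.13 ± 0.44), Acot2 (4.12 ± 0.50), Cbfa2t3 (3.84 ± 0.32), Spon2 (3.62 ± 0.31), Clstn3 (3.60 ± 0.38) and Cidec (3.54 ± 0.29) rose, as did the target genes Acot1 (3.16 ± 0.40), Vnn1 (2.43 ± 0.44), Ehhadh (2.30 ± 0.26), Cyp4a14 (1.94 ± 0.31), Cyp4a10 (1.60 ± 0.25), Fgf21 (1.41 ± 0.36, adjusted p = 0.00172) and Angptl4 (0.61 ± 0.14). Cpt1a had 0.14 ± 0.08 (adjusted p = 0.181). In all, 7024 genes passed (55.7%), 3695 higher and 3329 lower, and 809 changed at least by a log2 of 1.

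Falls in HZ with WY were led by the metallothionein Mt2 (-4.84 ± 1.17, adjusted p = 0.00108), Upp2 (-3.95 ± 0.59), Rgs16 (-3.70 ± 0.54), Zbtb16 (-3.52 ± 0.52), Mt1 (-3.27 ± 0.91, adjusted p = 0.00369), Cxcl1 (-3.20 ± 0.80), the phosphatidate phosphatase Lpin1 (-3.04 ± 0.42), Slco1a4 (-2.98 ± 0.32), Map2k6 (-2.73 ± 0.32) and Tmc7 (-2.66 ± 0.43). The metallothionein values rested on HZ vehicle animal 30: without it Mt2 had -0.91 (adjusted p = 0.189) and Mt1 -0.39 (adjusted p = 0.515), while Cxcl1 had -1.97 (adjusted p = 0.0148).

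By list, 22 of 27 peroxisomal genes rose and 4 fell with WY in HZ (the same adjusted over the list alone), with Acaa1a at 1.36 ± 0.07 and the thioesterase Acot8 at 1.72 ± 0.13. Of 23 genes of mitochondrial oxidation 20 rose and 3 did not pass (20 higher and 1 lower adjusted over the list alone), with Eci1 at 1.04 ± 0.08 and Etfb at 0.84 ± 0.07. Of 35 genes of lipid uptake, storage and release 27 rose and 3 fell, also adjusted over the list alone, with Mgll at 2.24 ± 0.17 and Slc27a1 at 1.76 ± 0.15. Camera gave adjusted p = 2.5e-08, 6e-09 and 2.5e-08 for these lists and adjusted p = 0.31, 0.23 and 0.19 with an estimated correlation. Of 31 genes of amino acid catabolism and the urea cycle 25 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 1e-07, adjusted p = 0.23 with an estimated correlation). Cps1 (-1.95 ± 0.17) was an example. Of 20 genes of bile acid synthesis and transport 14 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.19 with an estimated correlation). The hepatic organic anion importer Slco1b2 stood at -1.38 ± 0.12 and the conjugating enzyme Baat at -0.72 ± 0.08. Of 20 clock genes 14 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.23 with an estimated correlation). Nr1d2 stood at -0.91 ± 0.15 and Tef at -1.23 ± 0.23. Of 28 acute phase and complement genes 13 fell and 15 did not pass, also adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.57 with an estimated correlation). Crp stood at -1.24 ± 0.10 and complement C9 at -0.76 ± 0.09, and without HZ vehicle animal 30 the difference of the list means went from -0.53 to -0.26. Of 25 interferon response genes 5 fell and 20 did not pass (4 lower adjusted over the list alone), with Mx2 at -1.36 ± 0.26 and Ifi47 at -0.97 ± 0.20, and camera did not call the list (adjusted p = 0.098).

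**Figure D3:**
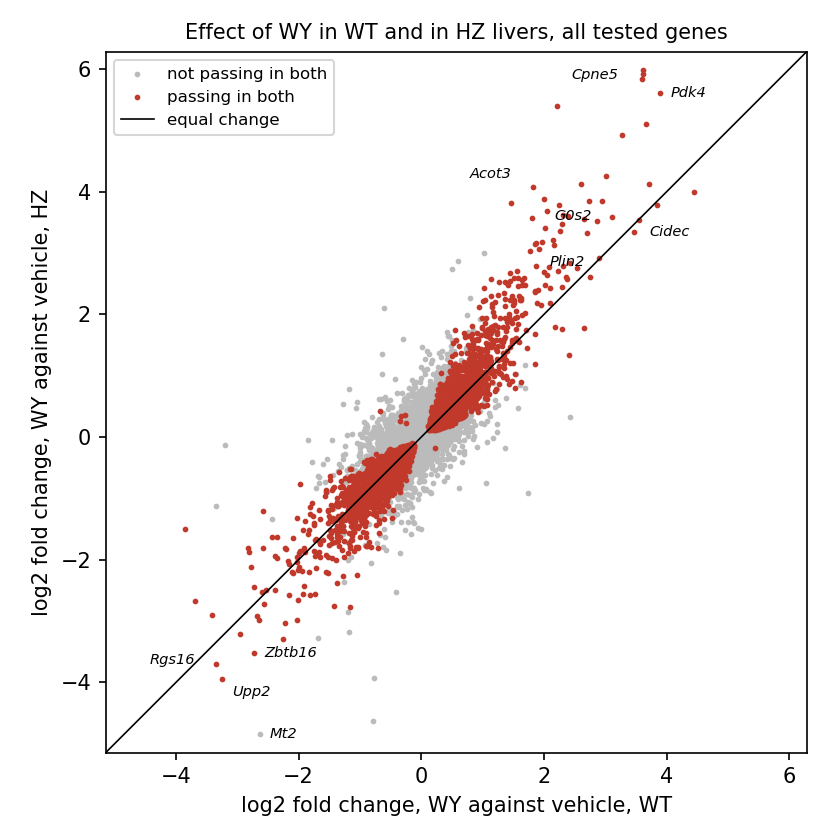
Log2 fold change of WY against vehicle in WT (horizontal) and in HZ livers (vertical) for the 12607 genes tested. Genes that passed in both are red, and the line marks equal change. Pdk4 lies at 3.89 in WT and 5.61 in HZ, and Upp2 at -3.25 and -3.95.

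WY moved most of the same genes in both genotypes. In WT and HZ alike 2921 genes rose and 2645 fell, against 1012 and 888 if the calls were independent, while 1 gene rose in WT and fell in HZ and 5 did the reverse. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.869. A shift between the vehicle and the WY count tables would be common to both genotypes and add to this agreement. The slope of the HZ change on the WT change was 1.15 over the 8357 genes that passed in the pooled WY effect, with a 95% bootstrap interval over animals from 0.974 to 1.36.

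The interaction asks whether WY acted differently in HZ and WT. Of the target genes none passed, though the fitted changes were larger in HZ. In other settings the sign turned for Fgf21 (-0.0896 with a clock score), Angptl4 (-0.0943 to -0.0461 in 3 settings) and Vnn1 (-0.0458 without the 5 HZ libraries). Acot3 had 2.27 ± 0.73 (adjusted p = 0.402), G0s2 1.88 ± 0.58 (adjusted p = 0.387), Pdk4 1.72 ± 0.77 (adjusted p = 0.506), Acot1 1.30 ± 0.53 (adjusted p = 0.474) and Plin2 1.14 ± 0.38 (adjusted p = 0.408). Cyp4a14 had 0.94 ± 0.42, Fgf21 0.88 ± 0.50, Ehhadh 0.82 ± 0.35, Cyp4a10 0.69 ± 0.35, Vnn1 0.33 ± 0.59, Angptl4 0.09 ± 0.19 and Cpt1a 0.09 ± 0.12. In edgeR 0 genes passed (1182 at an unadjusted p under 0.05, 630 by chance), against 3 with DESeq2 and 1 with limma and voom quality weights. Over the other settings, the number at an unadjusted p under 0.05 ran from 815 (clock score) to 2081 (voom quality weights). In edgeR with the clock score as a covariate the smallest adjusted p was 0.754. In the main fit the smallest p belonged to Dyrk2, a protein kinase (0.68 ± 0.13, adjusted p = 0.126). Dyrk2 was called by DESeq2 (adjusted p = 0.00985) and by voom (adjusted p = 0.00316), but not with the clock score. Next in the main fit were Proser1 (0.48 ± 0.10), Atxn1 (1.09 ± 0.23), Rqcd1 (0.37 ± 0.08) and Loxl4 (1.90 ± 0.45). With WY Dyrk2 fell by 0.33 ± 0.09 in WT and rose by 0.35 ± 0.09 in HZ. Proser1 fell by 0.25 ± 0.07 in WT and rose by 0.23 ± 0.07 in HZ, and Atxn1 fell by 0.67 ± 0.16 in WT and rose by 0.42 ± 0.16 in HZ. Rqcd1 rose in HZ by 0.46 ± 0.06, with 0.09 ± 0.06 in WT (adjusted p = 0.198), and Loxl4 rose in HZ by 1.60 ± 0.30, with -0.30 ± 0.33 in WT (adjusted p = 0.469). The peroxisomal list had a mean log2 CPM lower in HZ than WT by -0.58 under vehicle and -0.12 under WY. Its response in HZ exceeded that in WT by 0.45 ± 0.17 (permutation p = 0.0459, adjusted p = 0.433 over 36 lists), and camera gave adjusted p = 1.5e-05, or adjusted p = 0.63 with an estimated correlation, with 4 of 27 members higher adjusted over the list alone. The list of gluconeogenesis and glycogen genes had the smallest permutation p of the 36, at 0.00218 (adjusted p = 0.0785), with a response lower in HZ by -0.39 ± 0.12. In it Igfbp1 stood at -1.55 ± 0.50 (adjusted p = 0.402) and Pck1, the cytosolic PEP carboxykinase, at -0.88 ± 0.40 (adjusted p = 0.513). Neither list response passed over the 36 lists, and both shrank with the median of the members in place of their mean. The difference was then 0.104 for the peroxisomal list (permutation p = 0.584) and -0.0434 for the gluconeogenesis list (permutation p = 0.807). Other lists grew with the median. The clock list went from -0.233 to -0.622 (permutation p = 0.0175, adjusted p = 0.157). Lipid uptake, storage and release went from 0.252 to 0.595 (permutation p = 0.0376, adjusted p = 0.271).

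**Figure D4:**
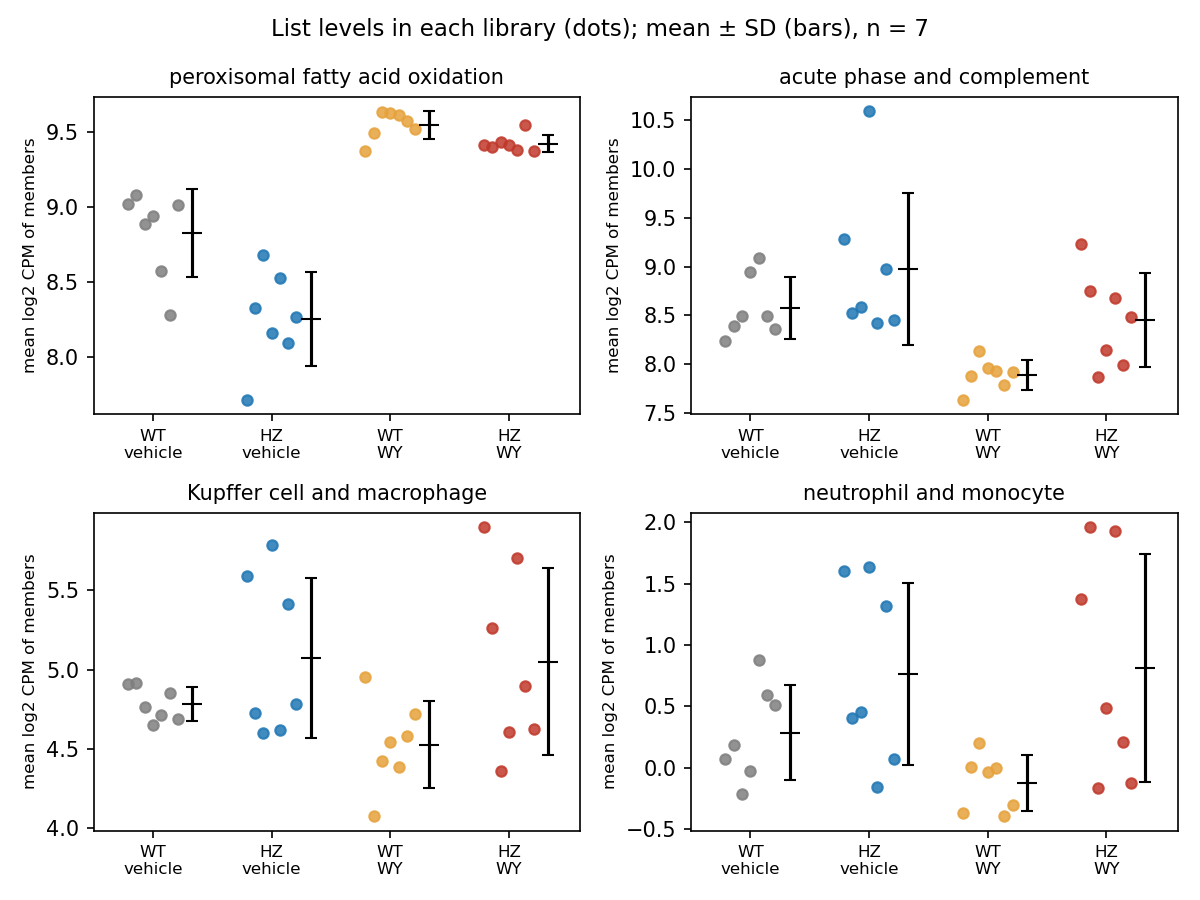
Mean log2 CPM of 4 gene lists in each library, by group (dots), with the mean ± SD of each group of 7 (bars). The peroxisomal list differs between HZ and WT by -0.58 under vehicle and by -0.12 under WY.

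The genes that were lower in HZ under vehicle were mostly genes that WY raised in WT. Of the 223 genes lower in HZ under vehicle, 203 rose with WY in WT, 2 fell and 18 did not pass, against 61.1 rises if the calls were independent. Of the 38 genes higher in HZ under vehicle, 22 fell with WY in WT, 0 rose and 16 did not pass, against 10.1 falls if independent. Both comparisons use the WT vehicle animals, which alone gives a positive correlation across genes, 0.50 in simulated counts with no effects, whereas the observed Pearson r was -0.44. It was -0.47 on average when the WT vehicle animals were split so that each comparison had its own (range -0.61 to -0.33 over 70 splits). The simulated genes varied independently of each other, and every split used the same HZ vehicle animals. These values and the counts under independence therefore do not cover genes that vary together between the vehicle animals. Under WY, 17 of the 223 lower genes were again lower in HZ (3.87 if independent) and 6 of the 38 higher genes were again higher (0.54 if independent). No gene passed in opposite directions, and 205 of the 223 and 37 of the 38 had the same sign under WY.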

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

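Apart from the counts over other splits of the animals and the term for animals numbered 71 to 78, the tests of this part were chosen after the results they weigh had been seen.

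Genes of fatty acid oxidation and lipid storage were lower in HZ than WT livers under vehicle, with a difference of -0.46 in the mean log2 CPM of 85 members of 3 lists (exact permutation p = 0.00583), and by -0.15 under WY (exact permutation p = 0.00524). A difference between animal number series was set against it, because 3 of 7 WT but 1 of 7 HZ vehicle animals carry numbers from 71 to 78, and among the 4 WT and 6 HZ animals numbered 29 to 39 alone the difference was -0.40 (exact permutation p = 0.00952). That argues against the series as the whole cause, although the share of the difference kept, 86.7%, had a bootstrap interval from 25.8 to 136%, so a part played by the series stays open. With a clock score as a covariate the difference was -0.38 (exact permutation p = 0.00699), and with a trend on transcript length removed the median log2 fold change was -0.35 against -0.36 before. That argues against the hour of sampling and against length as the whole cause. Vehicle animals numbered 71 to 78 had clock scores of 0.666 to 1.25, below all other vehicle animals except WT 29 (-0.547). Series and clock score were not adjusted for together, so a part played by the clock stays open too. The difference of these lists under WY was not adjusted for the clock score. That the Sirt6 genotype lowers these genes may be put forward as a hypothesis, while food intake before death, which is not given in the sources used here, was not tested.

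Acute phase genes and leukocyte markers stood higher in some HZ livers, by 0.48 for the acute phase list (permutation p = 0.00787) and 0.47 for 25 markers of macrophages, neutrophils and B cells (permutation p = 0.00901), as means over both treatments. A lower share of hepatocytes would raise every other cell type alike, but 13 markers of sinusoidal endothelium had 0.03, and the leukocyte value exceeded theirs by 0.43 (permutation p = 0.00469). These are means over all HZ animals. HZ WY animals 14, 15 and 21 had endothelial means of 5.16, 5.12 and 5.29, above every WT WY animal (highest 5.10). HZ vehicle animal 38 had 5.42 (highest WT vehicle animal 5.33), while animal 30, at 5.10, lay within the WT vehicle range. A lower hepatocyte share in single livers therefore stays open. More blood in the tissue would raise erythroid transcripts, but 3 erythroid markers had -0.12, and the leukocyte value exceeded theirs by 0.58 (permutation p = 0.0222). By cell type the values were 0.41 for Kupffer cell and macrophage markers, 0.71 for neutrophils and monocytes, 0.40 for B cells, 0.19 for stellate cells and fibroblasts and -0.09 for cholangiocytes. More leukocytes, or more active ones, in a few HZ livers (vehicle animals 30 and 38, WY animals 14, 15 and 21) may account for the pattern, and whether the genotype or an infection or lesion of single animals lies behind it was not tested.

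Nuclear genes of oxidative phosphorylation and other short transcripts were lower in HZ than WT under WY, where log2 fold changes correlated with log10 transcript length across genes at r = 0.226. With a trend on length removed the list median moved from -0.15 to -0.0895, the share of the mean difference kept was 51.3% (bootstrap interval 35.5 to 73.4%), and 2 of the 7 called members were still called, as their fold changes shrank. With a trend on GC content removed the median was -0.16 and 9 members were called, which argues against GC content. The lowest values lie in HZ WY animals 14, 15 and 21, the livers with more leukocyte transcripts. Without them the difference of the means was -0.0942 against -0.14, and leaving out the lowest animals must shrink it. A length effect of RNA quality or library preparation and a change of respiratory chain transcripts cannot be told apart here, because the interval spans the share of 50% set as the bound for the test.

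Other splits of the same animals into groups of the same sizes were fitted, 100 per comparison with the real split among them. For HZ against WT under vehicle 3 of 100 splits, the real one among them, gave at least 261 genes, and the highest other split gave 824. That share is under the bound of 1 in 20 set for this test. As splits unrelated to genotype reached as many genes, the count alone does not exclude chance. Of 9 splits with all 4 animals numbered 71 to 78 on the same side, 2 reached 261 and the other 7 gave 0 to 62 genes. The split with 824 genes, several times the real count, is of this kind and points to a structure of the samples. A term for these animals had 410 genes of its own. Among vehicle animals numbered 29 to 39 edgeR called 0 genes between HZ and WT (1579 at an unadjusted p under 0.05). For HZ against WT under WY 1 of 100 splits, the real split, reached 398 genes, and the highest other gave 1. For WY against vehicle 1 of 100 splits, the real one, reached 6815 genes in WT (highest other 4426) and 7024 in HZ (highest other 5212). The split with 4426 genes moved only 2 animals. That with 5212 moved 12, which is close to the real split with its sides exchanged. The median of the other splits was 0 genes in both genotypes. For the interaction the real split has 0 genes, so all 100 of 100 splits reach it by construction (highest other 275), and this count decides nothing.

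Within each group of 7, a library was taken as far from the others where the gap to its neighbour exceeded the 95% bound of Dixon's ratio of gap to range. Chance passes this bound in about 1 in 20 groups: of 216 combinations of 54 measures and 4 groups, 19 passed, against 10.8 by chance, in 12 libraries.

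HZ vehicle animal 38 had 16606 detected genes, against 15493 in the next. It was also highest for B cell markers, at a mean log2 CPM of 4.49 against 3.33, and lowest for nuclear genes of oxidative phosphorylation, at 6.85 against 7.06. HZ vehicle animal 30 had the highest acute phase mean, 10.6 against 9.28. HZ vehicle animal 71 had the highest Plin2, 833 CPM against 428, and the highest Angptl4, 262 CPM against 202. HZ vehicle animal 34 had the highest Vnn1, 222 CPM against 66.2. WT vehicle animal 76 had the highest interferon response, a mean log2 CPM of 3.80 against 2.42.

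WT WY animal 10 had the lowest fatty acid synthesis mean, 6.80 against 7.50. WT WY animal 11 had the highest mean of drug metabolism genes under CAR and PXR, 7.06 against 6.82. WT WY animal 19 had the highest mean of nuclear oxidative phosphorylation genes, 7.65 against 7.56, and of immediate early genes, 3.84 against 3.17. HZ WY animal 2 had the highest means for peroxisomal (9.55 against 9.43) and mitochondrial fatty acid oxidation (8.68 against 8.54) and the lowest for periportal hepatocyte genes (6.02 against 6.39). HZ WY animal 5 had the lowest cholangiocyte mean, 1.47 against 1.97. HZ WY animal 21 had the highest interferon response, 3.05 against 2.15, and the highest cell cycle mean, 2.14 against 1.76. HZ WY animal 15 had the lowest share of gene counts under names lost to dates, 0.224% against 0.235%. These lost names carry up to 0.246% of the gene counts of a library, a signal in data that could not be assigned to genes.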

How the results depend on the processing

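The settings without the 5 HZ libraries that stand apart, with only animals numbered 29 to 39, with length or GC trends removed and with the clock score were chosen after the results were seen, and the others were planned. For WY the number of genes moved little when a library of the groups compared was left out, within 6495 to 6757 in WT and 6658 to 7130 in HZ. Such counts do not show how many of the genes stayed the same between settings. The lowest counts in other settings were 5905 in WT (mean of at least 5 CPM, 9245 genes tested) and 5525 in HZ (clock score), apart from 625 and 809 with the added fold threshold, by its construction. Of the 61 and 64 genes called and named in the text, 55 and 56 kept their call in every leave-one-out and every setting that tested them, the fold threshold aside.

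For HZ against WT under vehicle the number of calls moved with the libraries used. The 261 genes became 35 with the fold threshold, 521 with DESeq2, 701 with voom quality weights, 146 without a filter (19225 genes tested), 69 with the term for animals 71 to 78, and 0 in edgeR with only the 14 vehicle libraries (1889 at an unadjusted p under 0.05), without the 5 HZ libraries (1297) or with animals 29 to 39 only (1579). Leaving out 1 library gave 43 (without WT 74 or HZ 38) to 650 (without HZ 71), with 47 without WT 76, 63 without WT 29, 80 without HZ 35, 112 without WT 78, 126 without WT 32, 129 without HZ 30, 161 without HZ 39, 453 without WT 37 and 609 without WT 31. Of the 34 genes called here and named in the text, 8 kept their call in every leave-one-out, 17 lost it with the term for animals 71 to 78, and all 34 lost it in the 3 settings with 0 genes. All 34 kept their sign in every leave-one-out (G0s2 -2.37 to -1.88, Plin2 -1.58 to -1.16, Acot3 -3.35 to -2.42). The median ratio of their folds to those reported was 0.842 without the 5 HZ libraries (SE ratio 1.06). It was 0.927 with animals 29 to 39 only (1.07) and 0.846 with the term for 71 to 78 (0.911). With only the vehicle libraries it was 0.995 (SE ratio 1.26), which follows from fitting a mean per group.

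For HZ against WT under WY the 398 genes became 13 with the fold threshold, 683 with DESeq2 size factors, 1123 with DESeq2, 934 with voom quality weights, 153 without a filter, 1038 with the clock score, 142 with the length trend removed and 48 without the 5 HZ libraries. Leaving out 1 library gave 74 (without WT 19) to 977 (without HZ 2), with 107 without HZ 21, 124 without WT 11, 126 without HZ 15, 159 without WT 10, 226 without WT 24 and 250 without HZ 5. Of the 31 genes called here and named in the text, 25 lost their call without the 5 HZ libraries and 15 with the length trend removed. The median ratio of folds was 0.939 (lowest 0.345) and 0.890 (lowest 0.446) there.

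The interaction had 0 genes in edgeR (1182 at an unadjusted p under 0.05), 3 with DESeq2, 1 with voom, and 1, Dyrk2, without HZ vehicle 71 or 30. At that unadjusted p it had 815 genes with the clock score, where the smallest edgeR adjusted p was 0.754, and 2081 with voom. Lists called by camera, 15, 11, 13, 12 and 9 in the 5 comparisons, became 0 in each with an estimated correlation and 6, 2, 19, 22 and 0 with fry, which asks another question, and 5 for the interaction without the 5 HZ libraries. Leaving out 1 library kept them within 11 to 15, 11 to 13, 12 to 13, 11 to 13 and 6 to 11.

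Directions reversed for a few genes. Saa2 in HZ against WT under vehicle, not called at 4.04, had -0.0776 with DESeq2, -0.36 without the 5 HZ libraries and -0.0527 to 4.61 over the libraries left out. Ddx3y, called at -0.31 with WY in WT, had 0.0147 with the GC trend removed. In the interaction Sirt6 had 0.00318 without the 5 HZ libraries, Fgf21 -0.0896 with the clock score, Angptl4 -0.0672 with the term for animals 71 to 78, -0.0461 without the 5 HZ libraries and -0.0943 with the clock score, and Vnn1 -0.0458 without the 5 HZ libraries, and the cause was not tested. No paired analysis was possible because each animal number occurs in a single group, and a covariate for sex was not run, as Y-linked genes were expressed in all libraries. Depth limits genes such as Sirt6, with 15 to 79 reads per library.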

Other observations

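The tests of this part on single libraries were chosen after the values were seen.

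Besides the pathways above, WY lowered periportal hepatocyte genes. Of 14 tested, 10 fell and 4 did not pass in WT, and 9 fell and 1 rose in HZ, both also adjusted over the list alone, with Cps1, Gls2 and the histidine ammonia-lyase Hal (-1.13 ± 0.13 in WT) as examples. Camera gave adjusted p = 0.00089 in WT and 0.0019 in HZ, with adjusted p = 0.39 and adjusted p = 0.23 with an estimated correlation. Ppargc1a, the PGC-1α coactivator of gluconeogenesis, fell by 2.01 ± 0.27 in WT and by 2.17 ± 0.26 in HZ. Of 15 genes of gluconeogenesis and glycogen 6 rose and 7 fell in WT, 2 rose and 6 fell in HZ, also adjusted over the list alone, and camera called the list in neither (adjusted p = 0.667 and 0.111). Pck1 fell by 1.77 ± 0.29 in HZ, and the glycogen targeting subunit Ppp1r3b fell by 1.42 ± 0.24 in WT. Of 21 genes of fatty acid synthesis 10 rose and 2 fell in HZ with WY, with Me1 at 1.59 ± 0.23, Acacb at 1.66 ± 0.27 and Elovl5 at 0.81 ± 0.16, and camera did not call the list (adjusted p = 0.14).

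The NAD pathway enzymes Kynu (-0.95 ± 0.07) and Ido2 (-0.65 ± 0.09) fell with WY in WT. The male-biased liver genes Slco1a1 (-1.43 ± 0.14) and Hsd3b5 (-1.80 ± 0.34) fell with WY in HZ, where 8 of 15 such genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.52 with an estimated correlation). Of 4 Y-linked genes 3 fell with WY in each genotype, among them Uty (-0.49 ± 0.08 in WT) and Ddx3y (-0.31 ± 0.07 in WT), and camera did not call the list (adjusted p = 0.15 in WT). The sign of Ddx3y in WT turned once the GC trend was removed. Of 25 interferon response genes 0 passed in edgeR in HZ against WT under WY, also adjusted over the list alone, with Cmpk2 at 0.68 ± 0.22 (adjusted p = 0.0687) and Ifi47 at 0.64 ± 0.21 (adjusted p = 0.0743). Camera placed that list higher in HZ (adjusted p = 6.4e-05, adjusted p = 0.66 with an estimated correlation), but without the 5 HZ libraries that stand apart it did not call the list (adjusted p = 0.0836). The difference of the list means was 0.44 with all animals, 0.28 without HZ WY animal 21, and 0.20 without 14, 15 and 21.

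HZ vehicle animal 38 had 12 genes at 5 CPM or more and at 5 times or more the level of any other library. Among them were Cybb at 311 CPM (61.7 in the next library), Ubd at 178 CPM (16.0), Cyp2d12 at 124 CPM (3.28), Rragd at 87.6 CPM (3.95), Ntrk2 at 58.3 CPM (7.59), Cap2 at 16.6 CPM (0.392), Tff3 at 8.02 CPM (0.417) and H19 at 7.52 CPM (0.894). HZ vehicle animal 30 had 4 such genes, with Saa2 at 2736 CPM (331 in the next library), Mt2 at 993 CPM (79.7), Mt1 at 968 CPM (117) and Nnmt at 135 CPM (25.9). WT vehicle animal 31, HZ vehicle animal 35 and HZ WY animal 14 had 1 each, and the other libraries had 0. The first principal component of log2 CPM held 46.4% of the variance, the second 9.77%. On the second component the scores were -32.4 for HZ vehicle animal 38, -24.7 for 30, -37.6 for HZ WY animal 21, -27.8 for 14 and -18.4 for 15.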
